A study of Saccharomyces cerevisiae with 36 samples.

How the data were processed

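S1Seq libraries of Saccharomyces cerevisiae in meiosis were analysed from the deposited tables of depth-scaled reads (RPM) at each position and strand. Cells had been pregrown in acetate medium and sporulated in potassium acetate at 30 °C, per the labels' protocols. Per the submitters' processing notes the build was sacCer2 and the tools included R 3.1.2; the aligner is not given in the sources used here. That the values are the authors' RPM per library over both strands was read from the deposited values, which sum to 99.88% to 99.99% of the library total, and in each library every value was a whole multiple of the worth of 1 read within a tolerance of 0.01. Whole reads were recovered from these steps for 100% of values. Of the columns in the tables, 4 matched no listed sample and were not used. In all 0 h and spo11-Y135F libraries no position held over 5 or 10 reads, a limit seen in the values that no label describes.

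The labels gave the genotype, hours in meiosis and replicate of all 36 libraries, 2 of each kind, called biological replicates. Each genotype is its own strain. The main fits have no replicate term. No label says what a replicate number marks. Deviations of same-numbered libraries from their group means correlated over 0.1 in all 3 pairs of wild type times (strength, r of 0.21 to 0.52) and of dmc1 null times (0.42 to 0.84), so comparisons across times of these genotypes were also fitted with a term for the number within each genotype, added after the data were seen. Between tel1 null times r was −0.064, and between exo1-D173A times, a single pair, 0.23. Between wild type and the dmc1 null r was 0.43 at 4 h and 0.51 at 6 h. Over all 70 pairs of groups of different genotypes the median was 0.091 (−0.43 to 0.60). The main dmc1 null comparisons with wild type leave the number out, and fits with a term for it over all libraries are among the alternatives. The exo1-D173A 2 h replicate 1 stands in another deposited table than the 0 and 4 h replicate 1, whereas all times of replicate 2 share a table, so for exo1-D173A the number was not read as a pair.

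The hotspot list, tests, contrasts, the rule for named hotspots and most alternatives were chosen before the data were examined. Hotspots were local maxima, at least 2000 nt apart, of a strand-switch score in the exo1-D173A 4 h libraries: signal of resection polarity minus signal of opposite polarity within 1000 nt. The threshold was 91.7, the 99.9th percentile of the maxima in the spo11-Y135F 4 h libraries, the fallback fixed for the case that repeat regions decide the highest maximum, which was 121 and lay near an end of chromosome 12. This gave 1175 hotspots, of which 1000 had no other within 3000 nt. The polarity ratio used signal at 100 to 2000 nt from all hotspots. Mean resection length was the mean distance of the resection-polarity profile at 100 to 2500 nt of isolated hotspots, less the level at 2500 to 3000 nt, with each position limited to the library's 99.9th percentile. The centre share was the background-subtracted signal within 100 nt of the centre as percent of that plus the tract.

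Hotspot strength was the RPM of resection polarity within 2000 nt of the centre and not past a neighbouring one. Log2 of RPM plus 5 was centred per library on its median deviation over hotspots, which gives the scaled RPM, and limma 3.58.1 (R 4.3.3, lmFit and eBayes with trend) tested it in one fit over all libraries after 0 h except spo11-Y135F. Fold changes are on that scale and understate changes of weak hotspots. Lengths per hotspot were tested likewise as log2 nt over the 500 strongest isolated hotspots. P-values were adjusted by Benjamini and Hochberg over hotspots. The design had foreseen counts for strength; the values turned out to be RPM, so limma became the main test, as the design provided. EdgeR 4.0.16 on the recovered reads, which the design named for counts, was listed as an alternative afterwards, and DESeq2 1.42.0 was planned. Permutation tests used 100000 permutations, two-sided (Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3); figures used matplotlib 3.10.9.

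After first fits a least signal for a hotspot length was set, 20 reads over background and a signal at least 1 times the background, because in simulated libraries too many unchanged hotspots were called at 2 h without it. Lengths outside the measured window were treated as missing. Both choices were made after results had been seen, and the counts without the least signal are given among the alternatives.

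The steps were tested on simulated data. Simulated mean lengths of 800, 450 and 700 nt were recovered within 1.8% in the main window, and 91.9% of 1175 simulated hotspots were found within 200 nt. For 700 nt with the reads of the wild type 2 h libraries, a window to 4000 nt gave 601 and 713 nt, and opposite polarity as background 654 and 676 nt. For exo1-D173A against wild type at 4 h, limma called 1.9% of unchanged hotspots, 82.4% of those with a 1.5-fold and 95.3% of those with a 2-fold change in length (439 hotspots tested). For the tel1 null against wild type at 2 h it called 11.7%, 81.0% and 82.4% (98 tested). For strength in the bas1 null against wild type at 4 h the shares were 0.72%, 50% and 94% (1175 tested), and in the dmc1 null 0.51%, 58% and 91%. For strength 100 hotspots were changed by each fold, so these shares do not hold where few hotspots change.

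The rule for named hotspots took, for each strength contrast, the 10 largest increases and the 10 largest decreases among those past the threshold whose libraries did not overlap, for each length contrast the 5 largest shifts each way, and the 10 highest scores. The text gives a subset of them. A stretch without reads was a run of 300-nt windows with at least 20 expected reads and at most 5% of them. Alternatives were other hotspot definitions, windows, backgrounds, pseudocounts, fits, tools and replicates left out. Gene lists had been fixed, but no annotation in sacCer2 coordinates was used here, so no list was tested and no hotspot is named by a gene. Reads ranged from 431750 to 15474756 per library. PCR duplicates cannot be told from independent ends in these tables.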

Results

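S1Seq maps the ends of the single-stranded tails that form when DNA at a meiotic double-strand break is resected. S1 nuclease removes the tails, an adaptor is ligated to the blunted ends, and each sequenced end marks where resection stopped. To the right of a break these ends read on the forward strand, to the left on the reverse strand, and this arrangement is called resection polarity here. The 36 libraries of budding yeast in meiosis covered wild type at 0, 2, 4 and 6 h and 7 mutants, with 2 biological replicates of each genotype and time. The mutants were a dmc1 null (0, 4, 6 and 8 h), spo11-Y135F (0 and 4 h), exo1-D173A (0, 2 and 4 h), a tel1 null (2 and 4 h), and sgs1-deltaC375, a bas1 null and an ino4 null (4 h). The reads recovered from the deposited values ranged from 431750 in spo11-Y135F 0 h replicate 1 to 15474756 in dmc1 null 4 h replicate 1. All positions are in sacCer2 coordinates, and errors are SDs of 2 replicates unless an SE is named. With 2 libraries against 2, an exact permutation test cannot give p below 0.333. Values per library were not tested between groups and are given with their SDs. Tests were the fits per hotspot and permutation or exact tests over chromosomes and hotspots.

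Libraries of 5 mutants held almost no reads at stretches where the other genotypes did. Dmc1 null libraries held 47 reads at chromosome 5, 548411 to 549512, where 3475 would match the other genotypes, and 1 at chromosome 12, 652284 to 652835, against 20.3. The tel1 null libraries held 6 reads at chromosome 2, 51071 to 57193, against 1504, and 5 at 57195 to 59341, against 633. The sgs1-deltaC375 libraries held 1 read at chromosome 13, 640938 to 643298, against 275. In the bas1 null libraries 15 reads fell at chromosome 11, 635436 to 637944, against 1290, and in the ino4 null libraries 2 fell at chromosome 15, 111431 to 111886, against 120. These stretches were found by a search over the genome, and no annotation in these coordinates was used to name the genes in them, so whether they are the genes on the labels was not checked. The search found none particular to spo11-Y135F or exo1-D173A.

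Breaks were read at 1175 hotspots, found in the exo1-D173A 4 h libraries as places where the forward-strand signal to the right and the reverse-strand signal to the left exceeded the opposite arrangement. The highest by the exo1-D173A score were chromosome 4 position 835825, with 1812 ± 166 RPM of resection polarity within 2000 nt in wild type at 4 h, chromosome 6 position 95877 with 2545 ± 378 RPM, and chromosome 7 position 610290 with 1490 ± 11.8 RPM. By wild type signal others stood higher than the first of these, among them chromosome 3 position 65685 with 2343 ± 392 RPM. Chromosome 3 position 91164 held 2602 ± 318 RPM, but also 2743 RPM of opposite polarity, so its signal had no net resection polarity. The spo11-Y135F strain carries a catalytically inactive form of the protein that makes meiotic breaks. At 4 h in it the places on chromosomes 4, 6 and 7 held 286 ± 7.44, 297 ± 137 and 244 ± 53.6 RPM. Over all hotspots the ratio of resection polarity to opposite polarity was 1.01 ± 0.0033 in spo11-Y135F at 4 h. At 0 h it was 1.03 ± 0.0092 in the dmc1 null, 1.04 ± 0.031 in spo11-Y135F and 1.04 ± 0.014 in exo1-D173A. The wild type 0 h libraries gave 1.05 and 1.17. In all 0 h and spo11-Y135F libraries no position held over 5 or 10 reads, whereas the highest in another library was 799. Whether taller positions had been left out of them is not known.

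In wild type, resection signal was present at 2 h and higher at 4 h, with a longer mean length at 4 h. The polarity ratio was 1.40 ± 0.28 at 2 h, 2.11 ± 0.17 at 4 h and 1.89 ± 0.27 at 6 h. Mean resection length at isolated hotspots was 708 ± 51.8 nt at 2 h, 829 ± 10.8 nt at 4 h and 834 ± 5.68 nt at 6 h. The difference between 2 and 4 h exceeded both SDs, and that between 4 and 6 h was smaller than the SD at 4 h. With signal counted to 4000 nt the 2 and 4 h lengths were 774 ± 112 and 887 ± 32.1 nt. With opposite polarity as background they were 639 ± 183 and 865 ± 15.7 nt. The 2 h libraries had polarity ratios of 1.20 and 1.60, the lower one close to the 1.17 of wild type 0 h replicate 2. Background-subtracted tract signal per isolated hotspot was 30.0 ± 13.6 RPM at 0 h, 83.6 ± 40.2 RPM at 2 h and 265 ± 3.28 RPM at 4 h. In spo11-Y135F at 4 h it was 12.7 ± 5.79 RPM. Part of the signal behind the 2 h length is thus at the level of 0 h libraries. Between 4 and 6 h no hotspot changed its relative strength by limma at an adjusted p of 0.05, with 86 of 1175 at an unadjusted p under 0.05. EdgeR on the recovered reads also called 0, DESeq2 called 4, and limma with the replicate numbers paired within each genotype called 4. In simulated libraries of this comparison, 94 of 100 hotspots with a 2-fold change and 55 of 100 with a 1.5-fold change were called. With fewer changed hotspots the adjusted threshold is stricter. These shares therefore do not hold for a comparison in which few hotspots change.

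**Figure D1:**
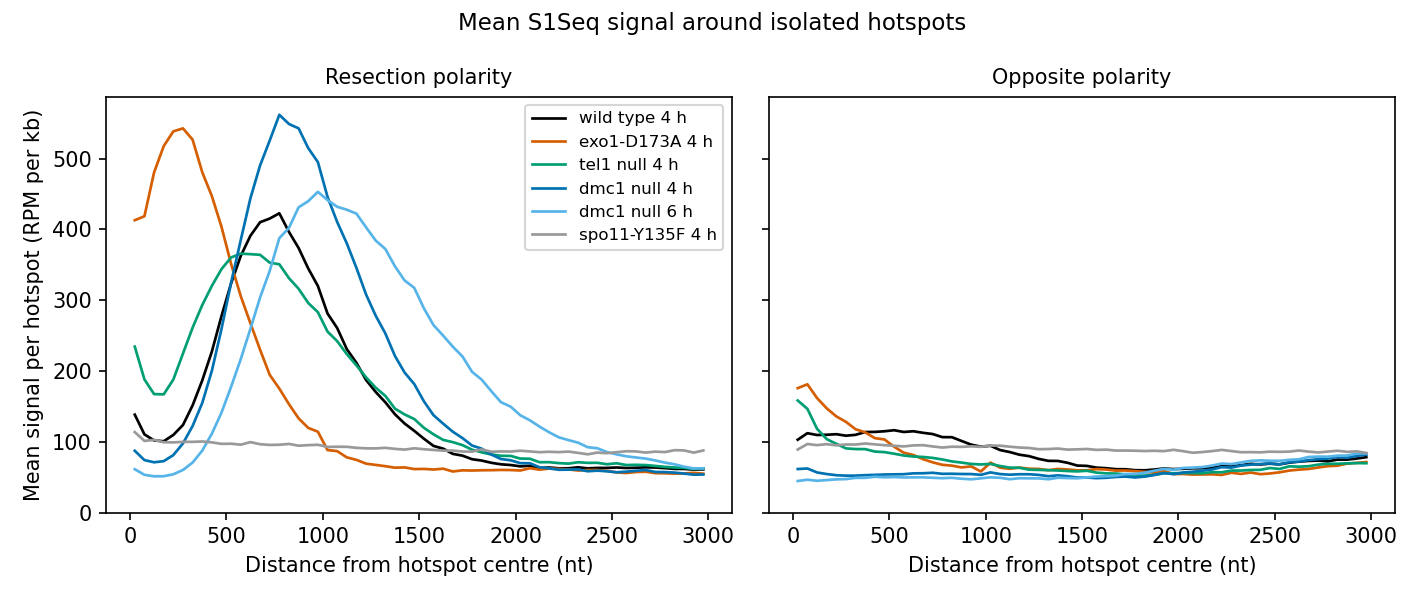
Mean signal per isolated hotspot (RPM per kb, 50-nt steps) by distance from the centre in nt, for resection polarity on the left and opposite polarity on the right; each line is the mean of 2 libraries. The exo1-D173A signal lies closest to the centre and the dmc1 null 6 h signal farthest from it, with mean lengths of 458 and 1216 nt, while spo11-Y135F is flat.

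In exo1-D173A, tracts at 4 h were shorter than in wild type at most hotspots with a measured length. Exo1 is a 5′ to 3′ exonuclease, and exo1-D173A removes its catalysis. At 4 h the mean length was 458 ± 16.3 nt, against 829 ± 10.8 nt in wild type, and at 2 h it was 432 ± 45.7 nt, against 708 ± 51.8 nt. At chromosome 4 position 212844 the length at 4 h was 139 ± 53.4 nt, against 704 ± 45.1 nt in wild type (log2 −2.39, SE 0.23), and at chromosome 14 position 642477 it was 129 ± 8.36 nt, against 641 ± 70.8 nt (log2 −2.31, SE 0.25). These exo1-D173A lengths lie near the start of the measured window at 100 nt, so the size of these differences depends on the window and the subtracted background. Signal within 100 nt of the hotspot centre made up 15.8% ± 0.058 of the total in exo1-D173A at 4 h and 3.87% ± 0.36 in wild type, and at 2 h 20.5% ± 1.97 and 8.25% ± 3.78. In RPM per hotspot it was 48.2 ± 2.41 and 10.7 ± 0.91 at 4 h, and 11.9 ± 0.45 and 6.69 ± 0.10 at 2 h. At 0 h it was 7.06 ± 1.01 in exo1-D173A, 2.87 ± 0.76 in wild type and 6.03 ± 0.85 in spo11-Y135F. Part of the centre signal at 2 h is thus at the level of libraries without breaks. Background-subtracted tract signal in exo1-D173A was 46.8 ± 7.40 RPM at 2 h and 16.7 ± 6.27 RPM at 0 h. The 2 h length thus also rests in part on signal at the 0 h level.

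By limma at 4 h, 374 of 403 hotspots were shorter and 0 longer (adjusted p under 0.05), with a median log2 change of −0.94. At 2 h, 22 of 30 were shorter and 0 longer, and chromosome 6 position 95877 measured 353 ± 115 nt, against 861 ± 16.7 nt in wild type. The change from 2 to 4 h differed from that of wild type at 1 of 30 hotspots, chromosome 9 position 36930 (log2 difference −0.80, adjusted p = 0.0024), a place named only because it was the single call. That call was absent without wild type 2 h replicate 2 or without exo1-D173A 2 h replicate 1, and without the latter 12 hotspots were shorter at 2 h. Few hotspots carried enough signal for a length at 2 h. Without a least signal, 122 were shorter and 11 longer of 362 at 2 h, and 362 shorter and 0 longer of 441 at 4 h.

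**Figure D2:**
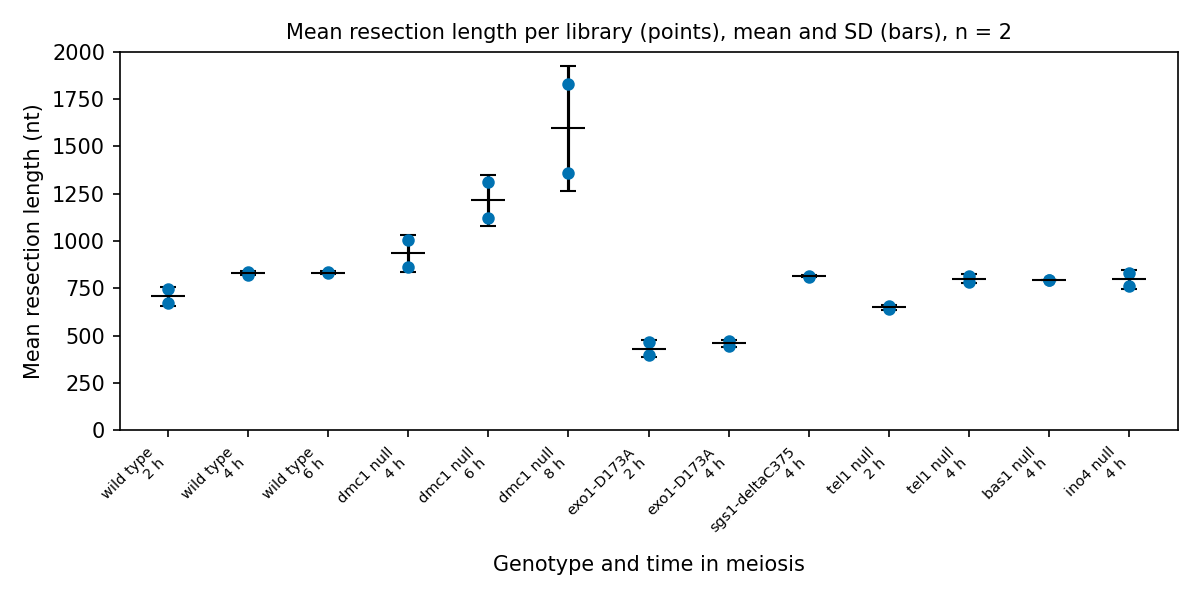
Mean resection length in nt for each library (points), with the group mean (horizontal bar) and SD (vertical bar), n = 2, by genotype and hours in meiosis. The exo1-D173A libraries lie between 399 and 470 nt, below all others, and the dmc1 null libraries lie at 865 and 1005 nt at 4 h and at 1362 and 1828 nt at 8 h.

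In the Sgs1 truncation mutant no change in resection length at a hotspot passed the test. Sgs1 is a RecQ helicase that can act in resection of breaks, and sgs1-deltaC375 carries a truncated form. Mean length was 814 ± 5.08 nt, against 829 ± 10.8 nt in wild type, a difference of −15.1 nt that exceeded both SDs and was 0.58 nt with opposite polarity as background. Lengths of single hotspots ranked as in wild type (Spearman's rho 0.95 over 376 hotspots, which are not independent replicates). The centre share was 4.72% ± 0.52, against 3.87% ± 0.36.

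By limma 0 of 376 hotspots were called in length, with 1 at an unadjusted p under 0.05, and 1 was called without a least signal for a length. In strength 1 of 1175 was lower, chromosome 13 position 645551 at 94.5 ± 13.4 against 174 ± 16.3 scaled RPM (log2 −0.85, SE 0.14, adjusted p = 0.012), which lies close to the stretch without reads at 640938 to 643298. EdgeR on the recovered reads called 2, DESeq2 13 and limma with library weights 20. The limma call was absent without sgs1-deltaC375 replicate 2 or without either wild type library.

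In the tel1 null, a larger share of the signal lay within 100 nt of hotspot centres than in wild type. Tel1 is the yeast ATM kinase. The centre share was 15.1% ± 4.04 at 2 h, against 8.25% ± 3.78 in wild type, and 7.38% ± 0.87 at 4 h, against 3.87% ± 0.36. Signal within 100 nt of the centre was 22.8 ± 3.90 RPM per hotspot at 4 h, against 10.7 ± 0.91 RPM. The polarity ratio at 4 h was 2.76 ± 0.14, against 2.11 ± 0.17. Mean length was 649 ± 12.3 nt at 2 h, against 708 ± 51.8 nt, and 800 ± 23.8 nt at 4 h, against 829 ± 10.8 nt. With signal counted to 4000 nt it was 958 ± 44.1 nt at 4 h, against 887 ± 32.1 nt, so the direction of the 4 h difference turned with the window. At 2 h the difference of −58.3 nt turned to 1.57 nt in that window and to 54.0 nt with opposite polarity as background.

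At 2 h, 13 of 114 hotspots were shorter and 0 longer by limma, among them chromosome 3 position 229018 at 445 ± 104 nt, against 722 ± 44.6 nt. In simulated libraries of this comparison 7 of 60 unchanged hotspots were called, with precision weights 0 of 114 passed, and without tel1 null 2 h replicate 2 or wild type 2 h replicate 2 the counts were 1 and 5. At 4 h 0 of 367 were called, with 59 at an unadjusted p under 0.05, and 29 longer and 88 shorter were called when only the tel1 null and wild type groups entered the fit. The change from 2 to 4 h differed from wild type at 0 of 112 hotspots, with 11 at an unadjusted p under 0.05.

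Relative strength in the tel1 null changed most on chromosome 3. The hotspot at position 65685 was at 137 ± 0.69 RPM at 4 h, against 2343 ± 392 RPM in wild type (log2 −4.11, SE 0.26), below the 253 ± 82.0 RPM of spo11-Y135F. Its neighbours at 74146 and 78238 were higher (log2 1.35 and 1.28), and position 93562 was lower (log2 −1.25). In wild type at 4 h position 93562 held 2165 RPM of resection polarity and 2437 RPM of opposite polarity. Its signal had no net resection polarity, so its decrease cannot be read as fewer breaks. Elsewhere, chromosome 6 position 131469 was higher at 4 h (620 ± 186 against 325 ± 29.7 scaled RPM), and chromosome 2 position 45313, a few kb from the stretches without reads, was lower (222 ± 5.29 against 525 ± 8.51). Chromosome 7 position 472713 was lower as well (272 ± 30.5 against 592 ± 43.5). At 2 h chromosome 3 position 40987 was higher (1305 ± 69.6 against 236 ± 17.3 scaled RPM, log2 2.44), and chromosome 14 position 498647 was lower (155 ± 4.55 against 281 ± 13.6).

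Limma called 10 hotspots higher and 12 lower of 1175 at 4 h, and 6 higher and 11 lower at 2 h. At 2 h the split was 19 and 4 when only these 2 groups entered the fit, and 12 and 9 with signal within 1000 nt. On RPM without rescaling the splits were 9 and 3 at 4 h, and 11 and 5 at 2 h. Without the hotspots of chromosome 3, the calls were 4 and 7 at 4 h, and 0 and 4 at 2 h. With opposite polarity subtracted first, 2 were called at 4 h and 103 at 2 h. With any one of the 4 libraries left out, 3 to 5 were called at 4 h. At 2 h, 68 were called without wild type replicate 2, 7 without its replicate 1, 5 without tel1 null replicate 2 and 11 without its replicate 1.

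In the dmc1 null, the resection signal was higher than in wild type, and tracts were longer at 6 h. Dmc1 is the meiosis-specific strand exchange protein. The polarity ratio was 4.02 ± 0.44 at 4 h, against 2.11 ± 0.17 in wild type, and 4.09 ± 0.21 at 6 h, against 1.89 ± 0.27. At 4 h background-subtracted tract signal per isolated hotspot was 388 ± 37.6 RPM, against 265 ± 3.28 RPM. Opposite-polarity signal at 100 to 1000 nt was 14.0 ± 0.55 RPM, against 57.4 ± 10.1 RPM, at the 600 hotspots isolated by 5000 nt. The level subtracted from it was that of resection polarity at 4000 to 5000 nt. The polarity ratio has opposite polarity as its denominator, so its rise partly reflects this lower signal. Mean length was 935 ± 99.0 nt at 4 h, 1216 ± 134 nt at 6 h and 1595 ± 330 nt at 8 h. With signal counted to 4000 nt these were 1035 ± 97.6, 1343 ± 148 and 1659 ± 210 nt. At 6 h chromosome 4 position 1242382 measured 1034 ± 120 nt, against 371 ± 69.2 nt in wild type, and chromosome 2 position 28888 measured 1317 ± 282 nt, against 509 ± 109 nt.

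By limma 317 of 372 hotspots were longer at 6 h than in wild type and 0 shorter, with a median log2 change of 0.54. Without dmc1 null 6 h replicate 1, 200 were called. At 4 h 0 of 417 were called, with 34 at an unadjusted p under 0.05. From 4 to 6 h the mean length changed by 306 and 256 nt within the replicate numbers of the dmc1 null and by 16.3 and −6.95 nt in wild type. The test of this difference per hotspot depended on the pairing of libraries: in the fit without pairs 0 of 369 hotspots passed, with 114 at an unadjusted p under 0.05, and with the numbers paired within each genotype 299 passed, all with more lengthening in the dmc1 null. The paired fit was added after the data were seen. Without pairs, adjusted calls numbered 107 without dmc1 null 4 h replicate 1 and 73 without dmc1 null 6 h replicate 2.

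The relative strength of hotspots differed between the dmc1 null and wild type at 4 h, and the higher ones lay mostly on long chromosomes. Hotspots at chromosome 7 position 733425 (1181 ± 52.1 against 625 ± 2.29 scaled RPM, log2 0.91, SE 0.17) and 610290 (2590 ± 362 against 1393 ± 10.9, log2 0.89) were higher, as was chromosome 4 position 755314 (187 ± 23.7 against 88.6 ± 8.33, log2 1.03). Lower were chromosome 9 position 53917 (1103 ± 66.3 against 2132 ± 208, log2 −0.95), chromosome 9 position 130110 (223 ± 15.2 against 418 ± 17.2, log2 −0.89) and chromosome 12 position 388439 (236 ± 8.32 against 520 ± 40.0, log2 −1.12). Of 71 higher hotspots, 69 were on the 8 longest chromosomes and 2 on the 8 shortest. Of 38 lower hotspots, 16 and 22 were. These chromosomes held 806 and 369 of the hotspots tested.

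The test was limma over 1175 hotspots, and edgeR called 65 higher and 64 lower. On RPM without rescaling, where the median change over all hotspots was 0.30 on the log2 scale, 328 were higher and 12 lower, so the changes above are relative to that shift. No hotspot was called when opposite polarity was subtracted first, 39 with signal within 1000 nt, 10 when only these 2 groups entered the fit, and 10, 53, 19 and 39 without wild type replicate 1, wild type replicate 2, dmc1 null replicate 2 and dmc1 null replicate 1.

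From 4 to 8 h in the dmc1 null, strength rose at 35 hotspots and fell at 39 relative to the others. Strength counts signal within 2000 nt of the centre and not past a neighbouring hotspot. Mean length rose over these times from 935 ± 99.0 to 1595 ± 330 nt. Longer tracts may carry signal out of this window or in from neighbours, so these calls cannot be told apart from tract lengthening. Chromosome 12 position 159733 rose from 138 ± 47.5 to 370 ± 154 scaled RPM (log2 1.37, SE 0.28) and chromosome 15 position 324631 from 175 ± 33.4 to 377 ± 67.1 (log2 1.08). Chromosome 11 position 24930 fell from 249 ± 36.6 to 96.2 ± 31.1 (log2 −1.35) and chromosome 1 position 42807 from 215 ± 83.4 to 78.7 ± 53.1 (log2 −1.50). By limma on RPM without rescaling, 14 rose and 103 fell around a median change of −0.22. With signal within 1000 nt 121 rose and 111 fell, with opposite polarity subtracted 11 and 74, and with the replicate numbers paired 82 and 116. Without dmc1 null 4 h replicate 2 no hotspot was called, without 8 h replicate 1 133 were, without 4 h replicate 1 50 were, and with only these 2 groups in the fit 0 were.

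The strains without the transcription factor Bas1 (purine and histidine synthesis genes) or Ino4 (phospholipid synthesis genes) differed from wild type in the strength of few hotspots, and no difference in tract length passed the test. Mean length was 794 ± 0.17 nt in the bas1 null and 798 ± 49.8 nt in the ino4 null, against 829 ± 10.8 nt. The difference of −34.8 nt in the bas1 null exceeded both SDs and was −3.24 nt with signal counted to 4000 nt, and that of −30.4 nt in the ino4 null was smaller than its SD. In the bas1 null, chromosome 11 position 589696 rose 2.41-fold (508 ± 21.6 against 209 ± 31.8 scaled RPM, adjusted p = 4.9e-05 by limma) and chromosome 4 position 147870 rose 2.05-fold. Chromosome 11 position 635126 fell to 91.5 ± 9.83 from 482 ± 125 scaled RPM. The bas1 null stretch without reads, 635436 to 637944, covers most of the window in which its right-hand signal is counted. Tracts on that side could give almost no reads, so this decrease alone cannot be read as fewer breaks. Chromosome 13 position 759285 fell to 389 ± 72.8 from 677 ± 43.1. In the ino4 null, chromosome 7 position 802084 fell to 315 ± 53.7 from 576 ± 41.9 scaled RPM (log2 −0.87, SE 0.16), chromosome 10 position 573106 to 565 ± 21.6 from 1152 ± 14.4, and chromosome 5 position 77749 to 263 ± 34.2 from 670 ± 232.

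The chromosome 3 hotspot at 65685 was at 154 ± 27.9 RPM in the bas1 null and 145 ± 16.1 RPM in the ino4 null, against 137 ± 0.69 RPM in the tel1 null at 4 h. In exo1-D173A, sgs1-deltaC375 and the dmc1 null at 4 h it held 1345 ± 123, 1635 ± 94.2 and 2002 ± 176 RPM.

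Limma called 16 higher and 10 lower of 1175 in the bas1 null, and 4 higher and 8 lower in the ino4 null. The lower ones in the bas1 null include chromosome 11 position 635126, whose window overlaps the stretch without reads. Without the hotspots of chromosome 3, 13 and 7 and 2 and 7 were called. Chromosome 4 position 1454674 was lower in both strains (log2 −0.84 and −0.92), against the same wild type libraries. On RPM without rescaling the splits were 5 and 6 around a median of −0.11, and 2 and 16 around a median of −0.18. With opposite polarity subtracted first, 7 and 4 were called. With library weights 54 higher and 46 lower were called in the bas1 null and 26 and 14 in the ino4 null, and with only the compared groups in the fit 57 and 29, and 31 and 14, so in these fits most ino4 null calls were higher. In length 0 of 346 and 0 of 338 hotspots were called, with 3 and 12 at an unadjusted p under 0.05. The bas1 null strength count was 3 and 5 without its replicate 2 or wild type replicate 2, and 14 without its replicate 1 or wild type replicate 1. The ino4 null count was 1, 3 and 1 without its replicate 1, its replicate 2 or wild type replicate 1.

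**Figure D3:**
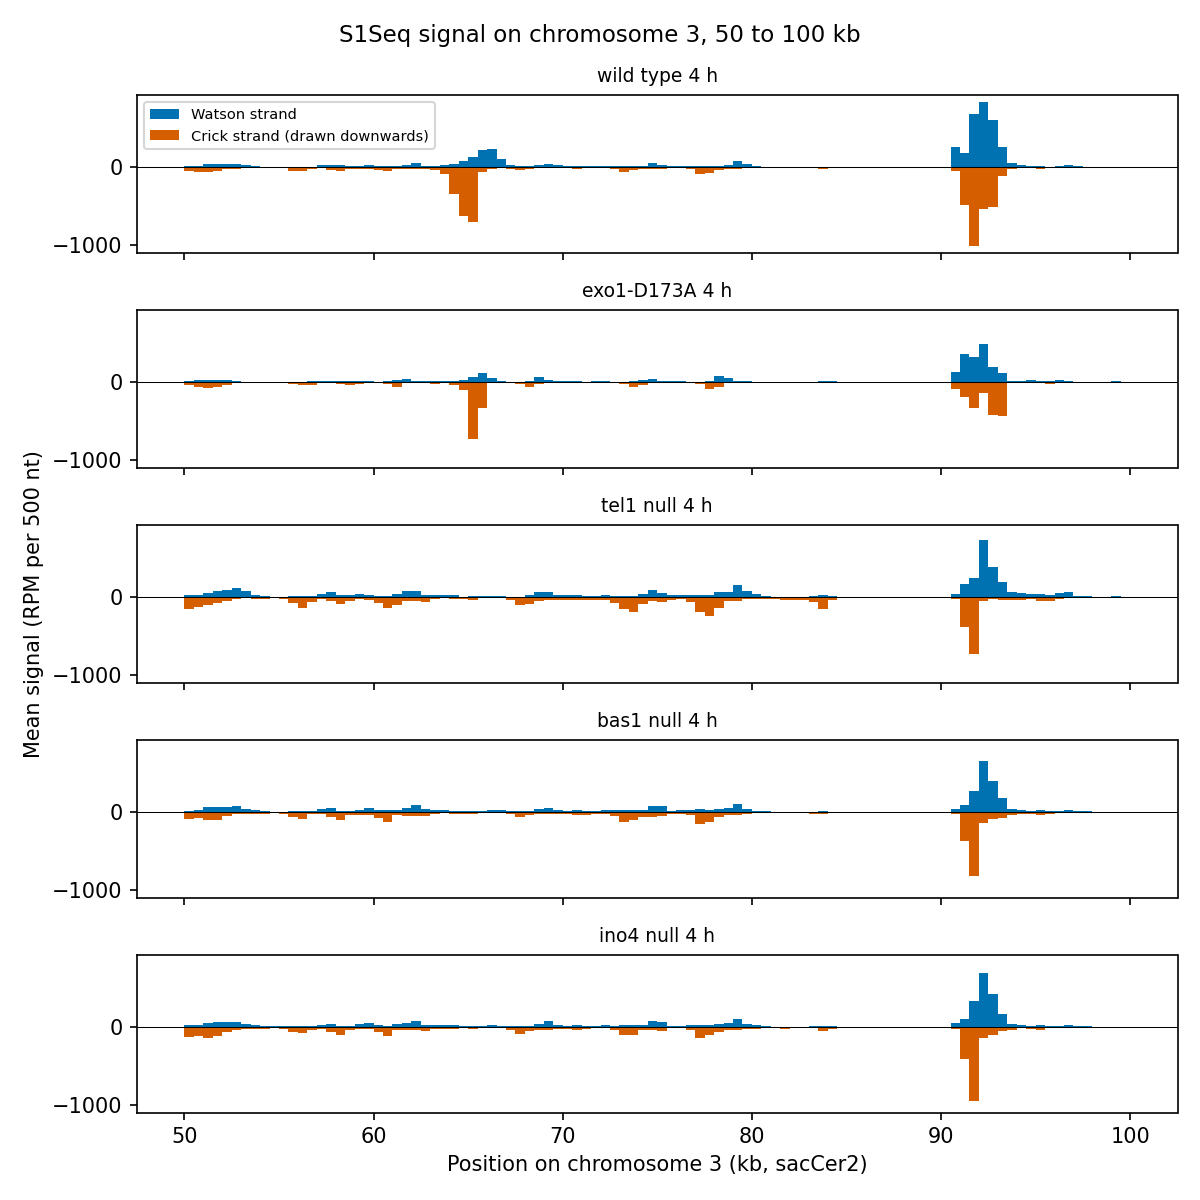
Signal on chromosome 3 from 50 to 100 kb in RPM per 500 nt, mean of 2 libraries, forward (Watson) strand upwards and reverse (Crick) strand downwards. The tracts around position 65685 are present in wild type and exo1-D173A and absent from the tel1, bas1 and ino4 null libraries.

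Shorter chromosomes carried more hotspot signal per kb in wild type. At 4 h the mean over the 3 shortest chromosomes (1, 6 and 3) was 62.4 RPM per kb, against 34.8 over the 3 longest (4, 15 and 7), and at 6 h 55.8 against 32.0. In the tel1 null at 4 h the means were 66.2 and 36.0. In the dmc1 null at 4 h they were 58.1 and 50.6, and at 6 h 51.8 and 49.4. Exo1-D173A at 4 h had 53.3 and 37.8.

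Over the 16 chromosomes the correlation of signal per kb with length was rho −0.96 and r −0.95 in wild type at 4 h (permutation p = 1e-05 for both, the smallest the 100000 permutations can give; adjusted over 10 groups, p = 3.3e-05). It was rho −0.95 and r −0.95 at 6 h and rho −0.89 and r −0.93 in the tel1 null at 4 h, with the same p. In the dmc1 null at 4 h it was rho −0.22 (p = 0.41) and r −0.35 (p = 0.18). Without the 2 chromosomes farthest from the median length, 1 and 6, r was −0.90 in wild type at 4 h, −0.91 at 6 h, −0.86 in the tel1 null at 4 h and 0.064 in the dmc1 null. In wild type at 2 h rho was −0.49 (p = 0.059) and r −0.70 (p = 0.0026), and in exo1-D173A at 4 h rho −0.51 (p = 0.048, adjusted p = 0.084) and r −0.70 (p = 0.0027). In the tel1 null at 2 h rho was −0.61 (p = 0.014, adjusted p = 0.035) and r −0.81 (p = 2.6e-04), and in exo1-D173A at 2 h rho was −0.49 (p = 0.057) and r −0.65 (p = 0.0071). Without chromosomes 1 and 6, r was −0.50 in wild type and −0.60 in the tel1 null at 2 h, and −0.24 and −0.30 in exo1-D173A at 2 and 4 h, so with these hotspots the exo1-D173A relations rest on those chromosomes. With wild type libraries defining the hotspots, rho was −0.90 and −0.84 in exo1-D173A at 2 and 4 h (p = 2.0e-05 and 1.0e-04), −0.89 in wild type at 2 h (p = 5.0e-05), −0.88 in the tel1 null at 2 h (p = 3.0e-05) and −0.55 in the dmc1 null at 4 h (p = 0.030). With dmc1 null libraries defining them it was −0.30 and −0.31 in exo1-D173A (permutation p = 0.26 and 0.24). Chromosomes of one genome are not independent samples of a group.

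**Figure D4:**
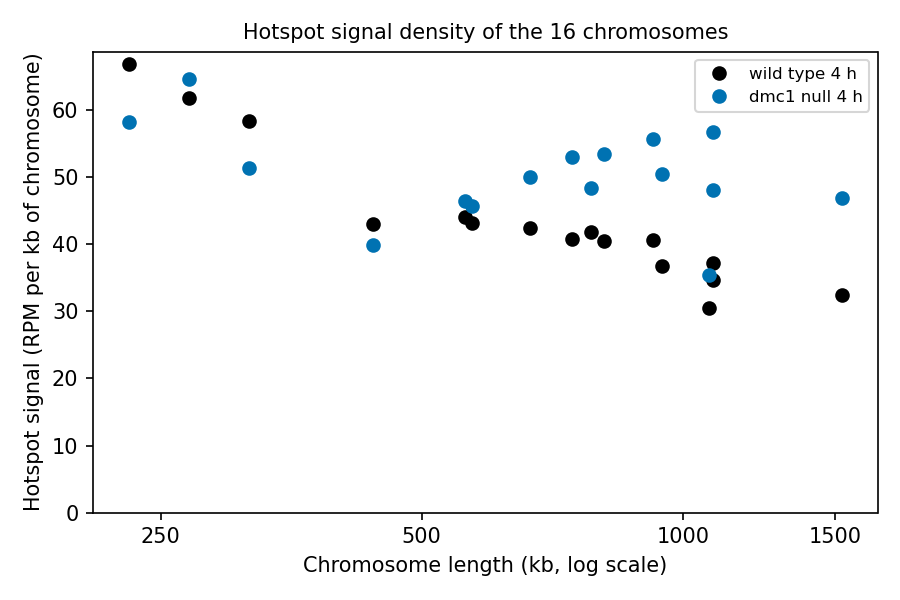
Hotspot signal in RPM per kb of chromosome against chromosome length in kb (log scale), one point per chromosome, mean of 2 libraries. Wild type at 4 h falls with length (rho −0.96), and the dmc1 null at 4 h does not pass the test (rho −0.22).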

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

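All tests of explanations in this part were chosen after the results were seen.

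Wild type 0 h replicate 2 had a polarity ratio of 1.17, above the highest spo11-Y135F library at 1.06. The limit of 5 reads a position is argued against by the other 4 libraries with it, whose highest ratio was 1.04. Reads carried over from a dmc1 null library may contribute: the best mixture held 6.52% of the dmc1 null 4 h signal (4.95 to 8.27) and 1.71% of the wild type 4 h signal (−1.35 to 4.67). Since wild type 2 h replicate 2 was also fitted by dmc1 null signal, at 25.4%, that source cannot be told apart from early tracts. Cells at the stage of the 2 h samples also stay open. The mean distance of the signal was 1063 nt (bootstrap interval over hotspots 999 to 1121). It was 539 and 826 nt in the 2 h libraries, which differ as widely from each other. Wild type gave 908 and 929 nt at 4 h and 926 and 919 nt at 6 h. The signal thus lay farther out than in any wild type library from 2 to 6 h. The dmc1 null 4 h libraries gave 1052 and 916 nt, and exo1-D173A 0 h replicate 1 gave 1010 nt (814 to 1153).

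The change in length from 2 to 4 h differed between exo1-D173A and wild type at 1 hotspot, chromosome 9 position 36930, by −0.80 on the log2 scale.

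Signal per kb depended on chromosome length differently in several mutants, by a test on the ratio of mutant to wild type over the 16 chromosomes, 6 ratios being tested. The correlation of that ratio with length was rho 0.92 for the dmc1 null at 4 h and 0.92 at 6 h, 0.84 for exo1-D173A at 4 h and −0.80 for the tel1 null at 2 h, with adjusted permutation p of 3.0e-05, 3.0e-05, 1.2e-04 and 6.1e-04. Pearson's r was 0.88, 0.92, 0.76 and −0.86 (permutation p of 1e-05, the smallest possible, for all but exo1-D173A at 6.4e-04), and 0.90, 0.91, 0.90 and −0.75 without chromosomes 1 and 6. Over single pairs of libraries rho ranged from 0.89 to 0.91, 0.82 to 0.93, 0.69 to 0.90 and −0.94 to −0.31. The tel1 null at 4 h (rho −0.15) and exo1-D173A at 2 h (rho −0.14) did not pass. Over single pairs of libraries their rho ranged from −0.34 to 0.15 and from −0.32 to 0.63. Without chromosomes 1 and 6 their r was 0.43 and 0.58, and with resection minus opposite polarity their rho was 0.0059 and −0.60.

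The chromosome 3 hotspot at 65685 was absent from the tel1, bas1 and ino4 null libraries. Omission of its reads during processing is argued against by the opposite-polarity level there, 188 RPM over the 8 libraries, close to the 248 RPM of spo11-Y135F at 4 h. The same libraries share another difference, 0 reads at chromosome 12, 459453 to 460892, where the others held 12260. Whether that comes from the strains or from processing was not tested. A sequence that the other strains carry at position 65685 and these strains lack, also read at a second place, is a candidate explanation: the hotspot at 93562 was lower in all 4 contrasts, least in the ino4 null at −0.62 on the log2 scale (adjusted p = 0.11 by limma there). Before rescaling, it held 1219 ± 105 RPM in the ino4 null and 2165 ± 471 RPM in wild type at 4 h. Wild type also held 2437 RPM of opposite polarity there, so the signal at 93562 cannot be read as break strength. The tel1 and bas1 null held 943 ± 28.7 and 1106 ± 82.0 RPM at 93562 at 4 h. In exo1-D173A, the dmc1 null and sgs1-deltaC375, which keep 65685, it held 1367 ± 127, 1624 ± 75.4 and 1876 ± 83.3 RPM. The sgs1-deltaC375 value lay within the SD of wild type. Exo1-D173A and the dmc1 null were lower along chromosome 3, with 1 and 0 of 15 hotspots over 100 kb from 65685 higher relative to the median change. These strains thus cannot show whether a lower value at 93562 is particular to those that lack 65685. An effect of each mutation cannot be told apart from such a missing sequence, since each genotype is its own strain. None of the 8 libraries kept a residue of the hotspot at 65685 (highest ratio to opposite polarity 1.07). Redistribution of breaks to neighbours may also occur: 4 of 4 hotspots within 20 kb were higher in each of the 3 genotypes at 4 h. All were set against the same wild type libraries, and 1 of 4 was higher in sgs1-deltaC375, which keeps the hotspot. At 20 to 50 kb 1 of 3 was higher in each of the 3 genotypes. It was position 40987, at 1230, 1021 and 1129 RPM in the tel1, bas1 and ino4 null, against 569 RPM in wild type. The others, 91164 and 93562, lie at or beside the second place, so these values cannot show where the rise ends.

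Opposite-polarity signal near hotspots was measured at 100 to 1000 nt, less the resection-polarity level at 4000 to 5000 nt. It was present in wild type at 4 h (57.4 ± 10.1 RPM per hotspot) and near background in the dmc1 null. Tracts of neighbouring hotspots are argued against by 64.0 RPM at hotspots isolated by 8000 nt. A spread of break positions within hotspots is argued against by the dmc1 null at 4 h, where this signal was 2.98% of the tract, against 18.1% in wild type. Structures that form only with Dmc1 stay open and had no test of their own, since the low level in the dmc1 null, 10.6 RPM at 6 h against 10.5 ± 3.32 in spo11-Y135F at 4 h, is the pattern itself. At 4 h exo1-D173A, sgs1-deltaC375, bas1, ino4 and tel1 mutants gave 46.5, 51.6, 48.0, 47.2 and 36.2 RPM.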

How the results depend on the processing

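Most alternatives were planned; edgeR, library and precision weights, the block within each genotype, no least signal, unrescaled RPM and leaving out chromosome 3 were added after seeing the data. In mean length, differences from wild type turned sign in sgs1-deltaC375, in the tel1 null at 2 and 4 h and in the ino4 null (1.38 nt with a window to 4000 nt, 4.77 nt without its replicate 1). In exo1-D173A the directions of length and centre share at 2 and 4 h were kept in every alternative run. So was that of length in the dmc1 null at 6 h. Besides leaving out replicates, counts of hotspots changed in strength moved in 59 of 122 alternatives. Where a replicate was left out, the lone library was assumed to vary like the other groups. Gene lists were not run. Differences are against wild type at the same time.

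Counts are listed below as moved where they changed more than 1.5-fold, so unlisted counts need not be equal. Other values are listed where they moved by the SD between replicates or more. For rho, a change of sign or of the test outcome was listed. For hotspots called in strength, the following moved. With hotspots from dmc1 null 4 h, 10 for tel1 null 2 h. With the 588 higher-scoring hotspots, 9 for tel1 null 2 h, 13 for tel1 null 4 h, 0 for sgs1-deltaC375 4 h, 71 for dmc1 null 4 h, 11 for bas1 null 4 h, 1 for wild type 6 against 4 h and 25 for dmc1 null 8 against 4 h. With the replicate block, 30 for tel1 null 2 h, 39 for tel1 null 4 h, 2 for sgs1-deltaC375 4 h, 188 for dmc1 null 4 h, 57 for bas1 null 4 h and 1 for wild type 6 against 4 h. With library weights, 11 for tel1 null 2 h, 63 for tel1 null 4 h, 20 for sgs1-deltaC375 4 h, 191 for dmc1 null 4 h, 100 for bas1 null 4 h, 40 for ino4 null 4 h and 0 for dmc1 null 8 against 4 h. With opposite polarity subtracted, 103 for tel1 null 2 h, 2 for tel1 null 4 h, 0 for sgs1-deltaC375 4 h, 0 for dmc1 null 4 h, 7 for bas1 null 4 h and 4 for ino4 null 4 h. Without the hotspots of chromosome 3, 4 for tel1 null 2 h and 11 for tel1 null 4 h. With edgeR, 10 for tel1 null 2 h and 2 for sgs1-deltaC375 4 h. With DESeq2, 48 for tel1 null 2 h, 57 for tel1 null 4 h, 13 for sgs1-deltaC375 4 h, 254 for dmc1 null 4 h, 68 for bas1 null 4 h, 30 for ino4 null 4 h, 4 for wild type 6 against 4 h and 164 for dmc1 null 8 against 4 h. With only the groups compared in the fit, 47 for tel1 null 4 h, 5 for sgs1-deltaC375 4 h, 10 for dmc1 null 4 h, 86 for bas1 null 4 h, 45 for ino4 null 4 h and 0 for dmc1 null 8 against 4 h. With signal within 1000 nt, 8 for tel1 null 4 h, 39 for dmc1 null 4 h, 13 for bas1 null 4 h and 232 for dmc1 null 8 against 4 h. With unrescaled RPM, 12 for tel1 null 4 h, 0 for sgs1-deltaC375 4 h, 340 for dmc1 null 4 h, 11 for bas1 null 4 h and 117 for dmc1 null 8 against 4 h. With hotspots from wild type 4 h, 0 for sgs1-deltaC375 4 h and 30 for dmc1 null 8 against 4 h. With the weakest hotspots left out, 0 for sgs1-deltaC375 4 h. With the replicate block within each genotype, 4 for wild type 6 against 4 h and 198 for dmc1 null 8 against 4 h. With one replicate left out in turn the range was 5 to 68 for tel1 null 2 h, 3 to 5 for tel1 null 4 h, 0 to 1 for sgs1-deltaC375 4 h, 10 to 53 for dmc1 null 4 h, 3 to 14 for bas1 null 4 h, 1 to 11 for ino4 null 4 h, 0 for wild type 6 against 4 h and 0 to 133 for dmc1 null 8 against 4 h.

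For hotspots called in length, the following moved. With only the groups compared in the fit, 13 for exo1-D173A 2 h, 0 for tel1 null 2 h, 117 for tel1 null 4 h, 3 for exo1-D173A from 2 to 4 h and 5 for tel1 null from 2 to 4 h. Without a least signal, 133 for exo1-D173A 2 h, 1 for sgs1-deltaC375 4 h, 73 for tel1 null 2 h, 14 for tel1 null 4 h, 6 for ino4 null 4 h, 96 for exo1-D173A from 2 to 4 h, 10 for tel1 null from 2 to 4 h and 1 for dmc1 null from 4 to 6 h. With a window to 4000 nt, 3 for exo1-D173A 2 h, 244 for exo1-D173A 4 h, 1 for tel1 null 2 h, 2 for tel1 null 4 h, 1 for dmc1 null 4 h, 2 for ino4 null 4 h, 0 for exo1-D173A from 2 to 4 h and 1 for tel1 null from 2 to 4 h. With opposite polarity as background, 11 for exo1-D173A 2 h, 6 for tel1 null 2 h, 1 for tel1 null 4 h and 2 for exo1-D173A from 2 to 4 h. With the 200 strongest hotspots, 185 for exo1-D173A 4 h, 20 for tel1 null 2 h, 11 for tel1 null 4 h, 180 for dmc1 null 6 h, 4 for exo1-D173A from 2 to 4 h, 1 for tel1 null from 2 to 4 h and 1 for dmc1 null from 4 to 6 h. With hotspots from dmc1 null 4 h, 8 for tel1 null 2 h, 6 for tel1 null 4 h and 4 for exo1-D173A from 2 to 4 h. With the 588 higher-scoring hotspots, 8 for tel1 null 2 h. With library weights, 32 for tel1 null 2 h, 16 for tel1 null 4 h and 3 for tel1 null from 2 to 4 h. With precision weights, 0 for tel1 null 2 h. With hotspots from wild type 4 h, 16 for tel1 null 4 h, 6 for dmc1 null 4 h, 3 for exo1-D173A from 2 to 4 h and 1 for tel1 null from 2 to 4 h. With the replicate block, 2 for exo1-D173A from 2 to 4 h. With the replicate block within each genotype, 5 for exo1-D173A from 2 to 4 h, 12 for tel1 null from 2 to 4 h and 299 for dmc1 null from 4 to 6 h. With one replicate left out in turn the range was 12 to 22 for exo1-D173A 2 h, 343 to 356 for exo1-D173A 4 h, 0 for sgs1-deltaC375 4 h, 1 to 12 for tel1 null 2 h, 0 to 1 for tel1 null 4 h, 0 to 3 for dmc1 null 4 h, 200 to 318 for dmc1 null 6 h, 0 for bas1 null 4 h, 0 for ino4 null 4 h, 0 to 2 for exo1-D173A from 2 to 4 h, 0 for tel1 null from 2 to 4 h and 0 to 107 for dmc1 null from 4 to 6 h.

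In the dmc1 null at 6 h the centre share was itself negative, −1.16% ± 1.02, against 4.23% ± 1.07 in wild type. There the subtracted level exceeded the centre signal, so the size of that difference depends on the background. For differences in centre share (points), the following moved. With centre within 50 nt, 5.99 for exo1-D173A 2 h, 5.93 for exo1-D173A 4 h, 2.09 for tel1 null 4 h, −1.66 for dmc1 null 4 h, −2.81 for dmc1 null 6 h and 0.63 for ino4 null 4 h. With centre within 200 nt, 24.1 for exo1-D173A 2 h, 25.3 for exo1-D173A 4 h, 5.05 for tel1 null 4 h, −5.71 for dmc1 null 4 h, −10.2 for dmc1 null 6 h and 1.63 for ino4 null 4 h. With hotspots from wild type 4 h, 14.0 for exo1-D173A 4 h, 0.31 for sgs1-deltaC375 4 h, 1.96 for tel1 null 4 h and 0.73 for ino4 null 4 h. With hotspots from dmc1 null 4 h, 13.3 for exo1-D173A 4 h, 2.25 for tel1 null 4 h and 0.84 for ino4 null 4 h. With a window to 4000 nt, 11.2 for exo1-D173A 4 h, 2.68 for tel1 null 4 h and −3.99 for dmc1 null 6 h. With one replicate left out in turn the range was 9.55 to 14.9 for exo1-D173A 2 h, 11.7 to 12.2 for exo1-D173A 4 h, 0.48 to 1.21 for sgs1-deltaC375 4 h, 4.04 to 9.76 for tel1 null 2 h, 2.89 to 4.12 for tel1 null 4 h, −3.52 to −2.69 for dmc1 null 4 h, −6.15 to −4.63 for dmc1 null 6 h, 0.25 to 1.43 for bas1 null 4 h and 0.88 to 1.39 for ino4 null 4 h.

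For differences in mean length (nt), the following moved. With a window to 4000 nt, −192 for exo1-D173A 2 h, 1.57 for tel1 null 2 h, 71.5 for tel1 null 4 h and −3.24 for bas1 null 4 h. With opposite polarity as background, −194 for exo1-D173A 2 h, −402 for exo1-D173A 4 h, 0.583 for sgs1-deltaC375 4 h, 54 for tel1 null 2 h and −2.45 for tel1 null 4 h. With median of the profile, −344 for exo1-D173A 2 h, −408 for exo1-D173A 4 h, −120 for tel1 null 2 h and −52 for tel1 null 4 h. With the 588 higher-scoring hotspots, −397 for exo1-D173A 4 h. With one replicate left out in turn the range was −313 to −239 for exo1-D173A 2 h, −382 to −359 for exo1-D173A 4 h, −22.7 to −7.53 for sgs1-deltaC375 4 h, −95 to −21.7 for tel1 null 2 h, −46.2 to −12.5 for tel1 null 4 h, 36.1 to 176 for dmc1 null 4 h, 287 to 477 for dmc1 null 6 h, −42.4 to −27.2 for bas1 null 4 h and −65.7 to 4.77 for ino4 null 4 h.

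For polarity ratios, the following moved. With hotspots from wild type 4 h, 2.36 for wild type 4 h, 2.19 for exo1-D173A 4 h, 2.23 for sgs1-deltaC375 4 h, 3.00 for tel1 null 4 h, 4.99 for dmc1 null 4 h and 2.16 for bas1 null 4 h. With the 588 higher-scoring hotspots, 2.36 for wild type 4 h, 2.68 for exo1-D173A 4 h, 2.25 for sgs1-deltaC375 4 h, 3.22 for tel1 null 4 h, 5.22 for dmc1 null 4 h, 2.19 for bas1 null 4 h and 2.22 for ino4 null 4 h. With hotspots from dmc1 null 4 h, 2.11 for exo1-D173A 4 h and 2.096 for sgs1-deltaC375 4 h. With one replicate left out in turn the range was 2.00 to 2.23 for wild type 4 h, 2.28 to 2.502 for exo1-D173A 4 h, 2.00 to 2.02 for sgs1-deltaC375 4 h, 2.66 to 2.86 for tel1 null 4 h, 3.71 to 4.33 for dmc1 null 4 h, 1.88 to 2.07 for bas1 null 4 h, 1.81 to 2.12 for ino4 null 4 h and 1.01 to 1.02 for spo11-Y135F 4 h.

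For rho with chromosome length, the following moved. With hotspots from wild type 4 h, −0.89 for wild type 2 h, −0.55 for dmc1 null 4 h, −0.62 for dmc1 null 6 h, −0.47 for dmc1 null 8 h and −0.90 for exo1-D173A 2 h. With hotspots from dmc1 null 4 h, 0.0029 for dmc1 null 4 h, 0.19 for dmc1 null 6 h and −0.31 for exo1-D173A 4 h. With resection minus opposite polarity, 0.29 for dmc1 null 4 h, 0.39 for dmc1 null 6 h, −0.60 for exo1-D173A 2 h and −0.39 for exo1-D173A 4 h. With the 588 higher-scoring hotspots, −0.053 for dmc1 null 8 h. With one replicate left out in turn the range was −0.53 to −0.49 for wild type 2 h, −0.96 to −0.93 for wild type 4 h, −0.95 to −0.86 for wild type 6 h, −0.27 to −0.24 for dmc1 null 4 h, −0.23 to 0.23 for dmc1 null 6 h, −0.37 to 0.54 for dmc1 null 8 h, −0.67 to −0.59 for tel1 null 2 h, −0.91 to −0.89 for tel1 null 4 h, −0.56 to −0.44 for exo1-D173A 2 h and −0.63 to −0.47 for exo1-D173A 4 h.

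Same-numbered libraries deviated together at a median r of 0.33 between times of one genotype (−0.064 to 0.84) and 0.091 between other groups (−0.43 to 0.60). The block within each genotype is read as a paired fit for wild type and dmc1 null times only, since exo1-D173A replicate 1 at 2 h stands in another deposited table than at 4 h and r was −0.064 between tel1 null times.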

Other observations

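The tests in this part were chosen after the results were seen. Over hotspots of wild type at 4 h, tract lengths of the 2 replicates correlated at rho 0.92 (373 hotspots), length correlated with strength at rho 0.52, and the 10% shortest lay below 620 nt and the 10% longest above 1009 nt. At 2 h the replicates correlated at 0.50 (62 hotspots). Lengths in exo1-D173A at 4 h correlated with those of wild type at rho 0.75 over 403 hotspots, and those of the tel1 null at 0.86 over 367. The left and right tracts of one hotspot were nearly uncorrelated in length in the wild type 4 h libraries, at rho 0.010 over 437 hotspots and 0.050 over 436. In exo1-D173A at 4 h it was 0.12 and 0.075. In the dmc1 null it was −0.31 and −0.11 at 6 h and −0.23 and −0.33 at 8 h, and in wild type at 2 h −0.13 and −0.21. The lengths of single sides were taken without a least signal and from centres placed in exo1-D173A. A misplaced centre lengthens one side and shortens the other, and replicate agreement of single sides was not measured. Low correlations therefore cannot show that the sides are independent. All these correlations are across hotspots, which are not independent replicates.

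The tel1, bas1 and ino4 null libraries also held 0 reads at chromosome 12, 459453 to 460892, 475674 to 476270 and 481559 to 482201, where the other libraries together held 12260, 196 and 719 reads. At the first stretch the lowest of the other libraries held 12.3 RPM, and at the later ones 0.

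Hotspots lower in the dmc1 null at 4 h were examined for position near chromosome ends. On the 8 longest chromosomes, 4 of 16 lower hotspots (25%) lay within 50 kb of an end, against 7.97% of the others, by Fisher's exact test p = 0.037, and adjusted over the 24 tests made p = 0.18. The share of lower hotspots did not pass the correction. The median log2 difference was −0.36 over the 67 hotspots near those ends and 0.15 elsewhere, and over all chromosomes −0.37 (124 hotspots) and 0.061. Of the 24 tests 4 passed: 0 of the 71 higher hotspots lay there, against 11.2% of the others (adjusted p = 0.011), and 0 of the 69 on the 8 longest chromosomes, against 9.09% (adjusted p = 0.032). The others were 10 of 39 hotspots that fell from 4 to 8 h in the dmc1 null, against 10.0%, and 3 of 4 higher in the ino4 null, against 10.3% (adjusted p = 0.032 for each). On the 8 longest chromosomes neither passed, with 4 of 22 against 8.04% (adjusted p = 0.33) and 1 of 2 (adjusted p = 0.36). The calls from 4 to 8 h numbered 0 with library weights or with only these groups in the fit. They also cannot be told apart from tract lengthening over these times. Hotspots are not independent, so these p-values are too small.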
